A study of Mus musculus with 2 samples.

How the data were processed

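Polyadenylated RNA was sequenced from the cortex of adult male mice of the strain B6NCrl, aged 8 weeks, in 2 libraries that the labels number as biological replicates 1 and 2. The labels call the tissue cortical plate in 1 field and adult cortex in another, and they give both libraries the same donor identifier while describing each as cortex of an individual mouse. The libraries form 1 group of 2, so no comparison between conditions exists, and every comparison between them describes these libraries, not conditions.

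The authors deposited a gene table and a transcript table per library. Per the file headers, the deposited tables give an expected count, TPM and FPKM for each feature, a posterior mean version of count and TPM, the bounds of an interval of TPM, and, for transcripts, the percent of the gene's TPM that each transcript holds. Per the labels and the libraries' text listings, reads were quantified on the mouse assembly mm10 with annotation M4, and replicates were not pooled. The aligner and the quantifier are not given in the sources used here. The deposited effective length was the length less 35 nucleotides for nearly every transcript. The 34 transcripts with another difference were at most 33 nucleotides long.

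Each gene table held 69691 rows, of which 43346 had Ensembl gene identifiers, 97 were spike-in sequences and 26248 were numbered rows with a mean length of 72.8 nucleotides. Analyses used the Ensembl gene rows. Symbols, gene types and coordinates came from GENCODE release M21, which uses the same build in a later release. Of the 43346 identifiers, 42462 (98.0%) matched without their version number and 884 did not. For every gene, the share of its 36-nucleotide words found in other genes' M21 transcripts was computed, as a measure of reads that cannot be assigned to 1 gene.

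Log2 ratios are of TPM + 1, replicate 2 over replicate 1. Gene counts and spreads use genes with a mean TPM of 1 or more unless stated, while list members were kept at any TPM. The pseudocount of 1 understates differences of genes at low TPM. Means are given ± SD with n = 2 libraries. A list median is the median of its members' mean TPM, given ± the SD of the 2 libraries' own medians. It need not lie between those library medians. Counting intervals are exact 95% binomial intervals, shares of a library have 95% Wilson intervals, and both cover counting error only, since the reads carry no molecular identifiers. Expected counts were rounded to whole numbers for edgeR 4.0.16 (R 4.3.3), which gave TMM factors and the common dispersion, whose square root is the biological coefficient of variation, and for DESeq2 1.42.0 as an alternative. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest. Ratios of TMM-scaled or DESeq2-scaled counts are of CPM + 1, which has no correction for length. No p-value was computed across genes.

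Marker lists were compared between the libraries by the percentile of their median log2 ratio among 10000 random lists of the same size, each member replaced by 1 of the 100 nuclear protein-coding genes nearest in mean TPM. The random lists treat genes as independent, whereas genes of 1 cell type vary together, so more lists fall outside the central 95% than chance alone would give. The steps were tested on a simulated pair of libraries with the real means and totals. With no gene changed and a coefficient of variation of 0.1 put in, edgeR returned 0.100 and DESeq2's median fitted value gave 0.162. With 220 genes changed, edgeR returned 0.134. In the simulated comparison of replicate 2 with replicate 1, run on 16362 genes, genes changed 1.5-fold, 2-fold, 3-fold and 4-fold were called over 2-fold apart in 4%, 42%, 100% and 100% of 50 genes each. Of 16142 unchanged genes, 400 were called, and of 11048 unchanged protein-coding genes with 100 or more counts, 1 was. A list raised 2-fold lay at the 100th percentile, and of 200 unchanged lists of 20 genes, 12 (6%) fell outside the central 95%.

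The tests, the gene lists and the rule for named genes were fixed before the data were examined. That rule names the 10 genes with the highest mean TPM, the 3 highest members of each list and up to 2 members under TPM 1 in both libraries, the 10 highest and 10 lowest log2 ratios among genes with a symbol, a mean TPM of 5 or more and 100 or more summed counts, the male sex chromosome genes with Xist, Nnt and Malat1, the leading transcripts of the isoform genes, and the 3 members with the largest absolute ratio in each list outside the central 95%. Genes named outside it are marked as chosen after their values were seen. Alternatives covered the TPM threshold, the pseudocount, the scaling, the low-value filter, the posterior mean values, FPKM, summed transcripts, the dispersion estimator, the summary over list members and each single library. A restriction to protein-coding genes with 100 or more counts, a rescaling over nuclear protein-coding genes, an adjustment for GC content, 10 further gene lists, the scaling alternatives for single genes and sums of the tested lists without the member with the most counts, and a comparison with lists of other kinds, were added after seeing the data. The depth was 13.2 M expected counts in replicate 1 and 14.7 M in replicate 2, so 3 counts correspond to a CPM of 0.227 and 0.205.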

Results

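RNA-seq of polyadenylated RNA was available from adult male mouse cortex at 8 weeks of age, as 1 group of 2 biological replicates. Replicate 1 held 13.2 M expected counts and replicate 2 held 14.7 M. The data address which genes the adult mouse cortex expresses and how closely the libraries resemble each other. A gene was called detected at TPM 1 or more in both libraries. This held for 15242 genes, of which 12600 were protein-coding, 822 were pseudogenes and 846 were long noncoding genes. A further 1024 genes reached TPM 1 in replicate 1 only and 1203 in replicate 2 only.

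The highest TPM values belonged to a few genes, most of them mitochondrially encoded. The 10 highest together held 36.9% of the TPM of all genes. The gene ENSMUSG00000045999, which has no symbol or gene type in the references used here, had a mean TPM of 85959 ± 3854 (SD, n = 2). Gm42418 had 79154 ± 15703 and Mir6236 had 44652 ± 10866. Mir6236 held 4.47% of the TPM but 0.275% of the counts, so its TPM rests on a short effective length. The mitochondrial ribosomal RNA mt-Rnr1 followed at 32384 ± 2338, and mt-Rnr2 had 18093 ± 805. Among the mitochondrially encoded protein genes, mt-Co1 had 26357 ± 2568, mt-Co2 22782 ± 5320.4 and mt-Co3 16327 ± 3756. The transfer RNA genes mt-Ts1 and mt-Tm had 26359 ± 8772 and 12703 ± 5361, values that rest on the very short effective lengths of such genes. Of these, mt-Co1, mt-Co2 and mt-Co3 shared 59.7%, 100% and 99.9% of their 36-nucleotide words with other genes, so their values are uncertain. Mitochondrially encoded genes took 13.2% ± 2.37 of the counts, Gm42418 took 9.86% ± 1.62 and nuclear protein-coding genes took 64.4% ± 0.848. Malat1, a nuclear long noncoding RNA, had a TPM of 3150.0 ± 235.

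Neuronal and glial genes were abundant in the cortex, and vascular genes were low. The excitatory neuron list had a median TPM of 61.4 ± 1.03 (SD of the libraries' medians, n = 2), led by the kinase gene Camk2a at 1331 ± 113, Nrgn at 793 ± 32.6 and the vesicular glutamate transporter gene Slc17a7 at 404 ± 36.3. Inhibitory neuron genes had a median of 22.9 ± 4.43, led by the neuropeptide gene Sst at 286 ± 57.9, the GABA synthesis gene Gad1 at 119 ± 25.9 and Npy at 97.8 ± 12.9. Astrocyte genes had a median of 66.98 ± 2.30, with the glutamate transporter gene Slc1a2 at 1097 ± 37.5, Aldoc at 497 ± 43.5 and Atp1a2 at 230.2 ± 38.5. Mature oligodendrocyte genes had a median of 72.1 ± 0.849, and the myelin genes Mbp, Plp1 and Mobp had 1019 ± 48.6, 493 ± 19.6 and 249 ± 5.66. Oligodendrocyte precursor genes had a lower median of 8.52 ± 0.0212, led by the lineage transcription factor gene Olig1 at 32.6 ± 0.559, Pdgfra at 13.5 ± 0.502 and Gpr17 at 12.96 ± 2.65.

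Microglial genes had a median TPM of 21.4 ± 1.26, led by Hexb at 48.6 ± 6.39 and the complement genes C1qb and C1qa at 26.5 ± 2.96 and 25.1 ± 4.02. Endothelial genes had a median of 3.39 ± 0.877, with the glucose transporter gene Slc2a1 at 24.9 ± 1.73, Ly6c1 at 17.5 ± 5.95 and Itm2a at 13.9 ± 1.54. Mural cell genes had a median of 6.26 ± 4.32 and meningeal fibroblast genes a median of 13.1 ± 6.82, and in both lists the libraries differed widely. The mural median was 8.54 in replicate 1 and 2.43 in replicate 2, and the meningeal median was 14.1 and 4.45. The pericyte genes Rgs5 at 17.1 ± 2.28 and Vtn at 16.4 ± 2.06 and the smooth muscle actin gene Acta2 at 9.24 ± 11.8 led the mural list. The prostaglandin synthase gene Ptgds at 375 ± 64.6, the growth factor gene Igf2 at 20.7 ± 3.63 and Igfbp2 at 17.96 ± 0.134 led the meningeal list. Blood cell genes had a median of 17.1 ± 2.84, with the haemoglobin genes Hbb-bs and Hba-a2 at 85.4 ± 25.9 and 63.6 ± 13.7 and Hbb-bt at 20.1 ± 0.424. Kcnj8 of the mural list, Lum of the meningeal list and Slc4a1 of the blood list were under TPM 1 in both libraries, at 0.745 ± 0.134, 0.815 ± 0.106 and 0.0300 ± 0.0141. Hba-a2, Hbb-bt, Hbb-bs and Igf2 shared 91.7%, 59.1%, 54.1% and 61.7% of their 36-nucleotide words with other genes, so their values are uncertain.

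**Figure D1:**
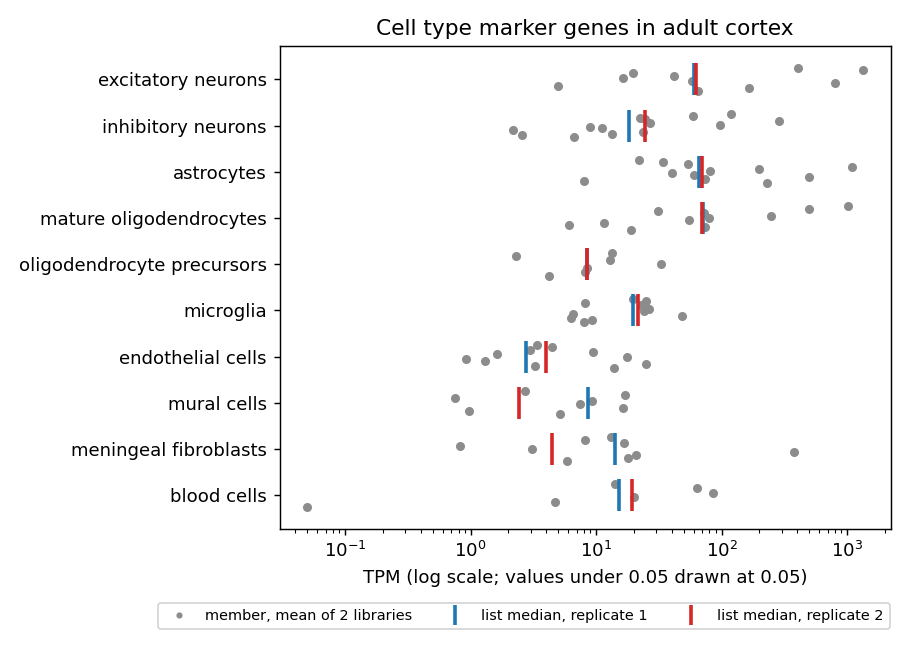
TPM of marker genes (log axis) for 10 cell types in adult cortex; grey points are list members as the mean of 2 libraries and bars are list medians in each library. Neuronal, astrocyte and mature oligodendrocyte medians lie between 18.4 and 71.2, and the mural and meningeal medians differ most between the libraries.

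Genes of all cortical layers were detected. Lamp5 at 86.9 ± 7.12, Rasgrf2 at 69.5 ± 6.59 and Calb1 at 50.8 ± 2.16 led the list for layers 2 and 3. Layer 4 was led by the nuclear receptor gene Rorb at 18.1 ± 1.32, Whrn at 9.43 ± 0.940 and Rspo1 at 1.74 ± 0.636. Layer 5 was led by the transcription factor genes Etv1 at 60.0 ± 2.81 and Bcl11b at 16.4 ± 3.03, with Parm1 at 16.6 ± 1.52. Layers 6 and 6b were led by Nr4a2 at 37.1 ± 6.88, Ccn2 at 14.9 ± 1.23 and Tle4 at 14.1 ± 1.84. Lists for other brain regions were mostly near or under TPM 1. The medians were 0.815 ± 0.00707 for the hippocampus, 0.667 ± 0.166 for the choroid plexus and ependyma, 0.468 ± 0.0636 for the olfactory bulb and 0.130 ± 0.0990 for the cerebellum. Their highest members were the dentate gyrus transcription factor gene Prox1 at 6.75 ± 0.0919, with Fibcd1 at 4.12 ± 1.46 and C1ql2 at 2.03 ± 0.269, the choroid plexus gene Ttr at 1.49 ± 0.184, with Foxj1 at 1.31 ± 0.453 and Ccdc153 at 1.07 ± 0.368, the mitral cell gene Cdhr1 at 1.20 ± 0.247, and Zic1 and Pcp2 of the cerebellum at 2.48 ± 0.827 and 1.17 ± 0.877. Under TPM 1 were Dsp at 0.510 ± 0.0283, Tdo2 at 0.815 ± 0.00707, Folr1 at 0.420 ± 0.594, Kl at 0.870 ± 0.0849, Eomes at 0.0650 ± 0.0919, Gabra6 at 0.0200 ± 0.0283 and Cbln3 at 0.130 ± 0.0990. Thalamic genes had a median of 4.66 ± 0.467, led by the glutamate transporter gene Slc17a6 at 8.23 ± 1.79, Tcf7l2 at 5 ± 0.170 and Plekhg1 at 4.70 ± 0.226, and striatal genes had a median of 16.6 ± 9.49, led by Penk at 126 ± 85.9, the dopamine signalling gene Ppp1r1b at 66.5 ± 39.3 and the phosphodiesterase gene Pde10a at 58.6 ± 28.1. Neural progenitor and cell cycle genes had a median of 0.710 ± 0.113, led by Hes5 at 7.08 ± 0.735, Pax6 at 5.81 ± 1.41 and the cyclin gene Ccnb1 at 2.06 ± 0.912, while the proliferation gene Mki67 was at 0.740 ± 0.212 and Nes at 0.710 ± 0.0707. Immature neuron genes were led by the tubulin gene Tubb2b at 99.0 ± 2.76, Nrep at 30.6 ± 1.64 and Dcx at 20.7 ± 0.240, and Igfbpl1 was at 0.255 ± 0.00707.

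Synaptic genes were among the most abundant. Presynaptic genes had a median TPM of 239 ± 15.5, led by Snap25 at 1461 ± 17.1, Syp at 709.9 ± 57.8 and Vamp2 at 619 ± 42.0. Postsynaptic genes had a median of 147 ± 5.41, with the scaffold gene Dlg4 at 457 ± 16.6 following Camk2a and Nrgn. All 12 listed GABA-A receptor subunit genes were detected, led by Gabrb3 at 159.9 ± 0.453, Gabra1 at 132 ± 7.23 and Gabrg2 at 93.2 ± 1.96. The subunit gene Gabra6, placed in the cerebellum list, was not detected. All 15 listed glutamate receptor subunit genes were detected, led by Gria2 at 263 ± 3.55, Gria1 at 172 ± 30.4 and Grin2b at 164 ± 3.59. Cck was the highest neuropeptide gene at 423 ± 17.3, followed by Sst and Penk.

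Activity and stress genes were present at varied levels. Egr1 at 46.3 ± 0.382, Egr3 at 30.8 ± 4.38 and Arc at 21.3 ± 6.84 led the immediate early genes, which respond to neuronal activity. Tef at 152 ± 2.54, Nr1d1 at 42.1 ± 3.39 and Cry2 at 34.4 ± 3.13 led the circadian genes. The kinase gene Sgk1 at 64.1 ± 2.16, Tsc22d3 at 32.6 ± 4.03 and Ddit4 at 20.1 ± 1.01 led the glucocorticoid response genes. The chaperone genes Hsp90aa1 at 1003 ± 73.8, Hsph1 at 144 ± 28.9 and Dnajb1 at 18.6 ± 3.16 led the heat shock genes. Interferon response genes were low, with a median of 1.40 ± 0.431, Stat1 at 7.53 ± 0.544, Ifit3 at 3.17 ± 0.240 and Isg15 at 1.65 ± 0.0354, and Ifit1 and Irf7 under TPM 1 at 0.850 ± 0.113 and 0.275 ± 0.0212. Cytosolic ribosomal protein genes had a median of 172 ± 6.84, led by Rplp1 at 645 ± 59.9, Rps29 at 322 ± 60.4 and Rpl38 at 292 ± 32.8. Of the RNAs without a long poly(A) tail, Rn7sk was highest at 1196 ± 85.4, followed by Rn7s1 and Rn7s2, each at 852 ± 156, which the files give the same values. Values are uncertain for Hsp90aa1, Ifit3, Rplp1, Rn7sk, Rn7s1 and Rn7s2, which shared 50.2%, 58.5%, 70.5%, 70.6%, 100% and 100% of their 36-nucleotide words with other genes.

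The labels give both libraries as male. Xist, which is expressed from the inactive X chromosome of females, had a TPM of 0.1 in replicate 1 and 0.110 in replicate 2. The Y-linked genes Ddx3y, Kdm5d, Uty and Eif2s3y had 20.3 ± 1.06, 11.1 ± 0.537, 10.9 ± 1.52 and 36.4 ± 10.1. Nnt, a mitochondrial transhydrogenase gene that is partly deleted in a related substrain, had 10.8 ± 0.530.

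The libraries were close for well-measured protein-coding genes. Across 16303 genes with a mean TPM of 1 or more, Pearson's r of log2(TPM + 1) was 0.966 and Spearman's rho was 0.967; genes are not independent replicates. The median absolute log2 ratio was 0.18. There were 712 genes over 2-fold apart, 395 of them higher in replicate 2 and 317 higher in replicate 1. The number was 168 with TMM-scaled counts, 102 from a mean TPM of 10, 396 with posterior means, 1091 with a pseudocount of 0.1 and 1263 with no filter on low values. The 168 rests on CPM + 1 without correction for length, and the TMM factors were 0.994 and 1.006. It therefore does not show an effect of scaling alone. In the simulation 400 of 16142 unchanged genes were called, so part of the 712 is expected without any change. The median summed count of the genes over 2-fold apart was 6.18, against 388 for the other genes. Among 11268 protein-coding genes with 100 or more counts, a restriction made after seeing the data, 44 were over 2-fold apart. Of these, 20 were higher in replicate 2 and 24 higher in replicate 1. The median log2 ratio of all genes was 0.10 on the TPM scale and 0.01 on the TMM scale. The biological coefficient of variation was 0.0947. It includes any difference in dissection or preparation, and the shared donor identifier leaves unclear whether it holds variation between animals. The counts of 18382 genes with 10 or more reads had a chi-square of 12.1 per degree of freedom, which includes errors in assigning reads to genes that share sequence. For 11255 nuclear protein-coding genes with 100 or more counts it was 5.08, still above the 1 that sampling noise alone would give.

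**Figure D2:**
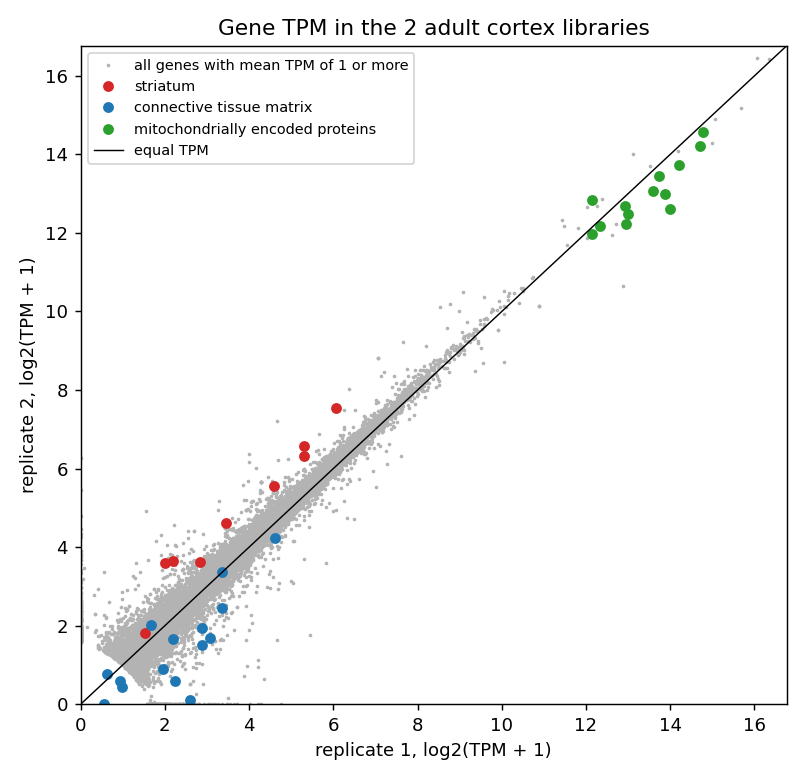
TPM of each gene in replicate 1 (x axis) and replicate 2 (y axis), both as log2(TPM + 1), with 3 gene lists in colour and a line of equal TPM. The 9 striatal genes lie above the line, 12 of 15 connective tissue matrix genes (a list added after seeing the data) lie below it, and 12 of 13 mitochondrially encoded protein genes lie below it.

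By list median, striatal genes differed most between the libraries, although some single genes outside that list differed more. All 9 members of the striatum list were higher in replicate 2, 5 of them over 2-fold, with a median log2 ratio of 1.16 at the 100th percentile of random lists. The adenosine receptor gene Adora2a (ENSMUSG00000020178.5, chromosome 10, 75316877 to 75334784) was higher by 3.75-fold (95% counting interval 2.88 to 4.95), the dopamine receptor gene Drd2 by 3.24-fold (95% counting interval 2.36 to 4.52) and the enkephalin precursor gene Penk (ENSMUSG00000045573.9, chromosome 4, 4133531 to 4138819) by 2.85-fold (95% counting interval 2.60 to 3.13). The neuropeptide list was higher as well, with a median of 0.38. It shares Penk with the striatum list and Sst, Npy, Vip and Crh with the inhibitory neuron list, so it is not independent of either. The other neuropeptide genes with the largest ratios were Nts at 1.21 and Tac1 at 1.07. Inhibitory neuron genes were higher, with a median of 0.47 and 12 of 14 members higher, among them Dlx2 at 0.78, Calb2 at 0.73 and Lhx6 at 0.68. With TMM-scaled counts that median was 0.24, and Dlx2, Calb2 and Lhx6 were at 0.27, 0.65 and 0.33. The 2 lower members, named after their values were seen, were Pvalb at -0.19 and Vip at -0.05 on the TPM scale. A cortical interneuron list added after seeing the data had a median of 0.10, inside its random lists at the 37.2 percentile. The inhibitory list therefore does not show that cortical interneuron genes as a set were higher. All 11 endothelial genes were higher on the TPM scale, with a median of 0.36, led by Ly6c1 at 0.67, Pecam1 at 0.57 and Abcb1a at 0.52. With TMM-scaled counts these were at 0.29, 0.26 and 0.51 and Slco1a4, chosen after its value was seen, was at -0.04, so the count of higher members and the leading genes depend on the scale. The mean over the neuropeptide members was 0.54. Over the alternatives the medians ranged from 1.02 to 1.23 for striatum, 0.25 to 0.40 for neuropeptides, 0.24 to 0.50 for inhibitory neurons and 0.24 to 0.54 for endothelial cells. The scaling and GC alternatives shift all genes as well, so these medians do not share 1 centre.

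Other lists lay on the lower side of their random lists. The median log2 ratio was -0.08 for mature oligodendrocytes, with Opalin at -0.37 but Cnp at 0.24 and Mog at 0.23, and -0.01 for excitatory neurons, with Neurod6 at -0.34, Satb2 at -0.23 and Nptx1 at 0.20. It was -0.12 for meningeal fibroblasts, where the collagen genes Col1a1 and Col1a2 were at -3.03 and -2.29 and Nupr1 at -0.61 while Ptgds was at 0.35, and the mean over members was -0.60. It was -0.18 for neural progenitors and cell cycle, -0.00287 for GABA-A receptor subunits, 0.03 for cytosolic ribosomal proteins, -0.23 for RNAs without a poly(A) tail and -0.18 for the Y-linked genes. The members with the largest ratios were Cdk1 at -0.67, Ccnb1 at -0.62 and Pax6 at 0.43 among progenitor genes, and Gabrd at 0.25, Gabrb1 at 0.17 and Gabrg1 at 0.12 among GABA-A subunits. They were Rps29 at -0.38, Rpl19 at -0.37 and Rpl8 at 0.29 among ribosomal genes, Rmrp at -1.003, Rn7s1 at -0.37 and Rn7s2 at -0.37 among RNAs without a poly(A) tail, and Eif2s3y at -0.56, Uty at -0.26 and Ddx3y at -0.10 among Y-linked genes. The ratios of Rpl19 and Rmrp are uncertain, as 58.1% and 100% of their words are shared, and so are those of Rn7s1 and Rn7s2. The random lists held protein-coding genes, whereas several RNAs without a poly(A) tail, such as Rmrp and Rn7sk, are noncoding. Among genes with a mean TPM of 1 or more, 48.5% of small RNA genes were over 2-fold apart, against 0.697% of protein-coding genes. The percentile of the list of RNAs without a poly(A) tail is therefore uncertain. In all, 12 of 35 lists lay outside the central 95% of random lists, against 1.75 if genes were independent. Of those 12, 5 moved inside in 1 or more alternatives. The other 23 lists, among them astrocytes at 0.13, microglia at 0.21 and all 4 layer lists, lay inside. Of those 23, 7 moved outside in 1 or more alternatives, among them layers 2 and 3 after an adjustment for GC content, at the 0.965 percentile. Meningeal fibroblasts, GABA-A receptor subunits and Y-linked genes moved inside after an adjustment for GC content, with percentiles of 2.96, 12.9 and 7.46. The adjustment shifts all genes, so each median was measured from the median of its random lists. That distance went from -0.23 to -0.16, from -0.12 to -0.06 and from -0.28 to -0.14. Each distance shrank with the adjustment, and what was left lay within the random lists. The meningeal median before the adjustment was the value of 1 gene, Lum, with 17 and 15 counts, so its change is uncertain. The mean over the meningeal members, -0.60 without the adjustment, lay at the 0 percentile of random lists.

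**Figure D3:**
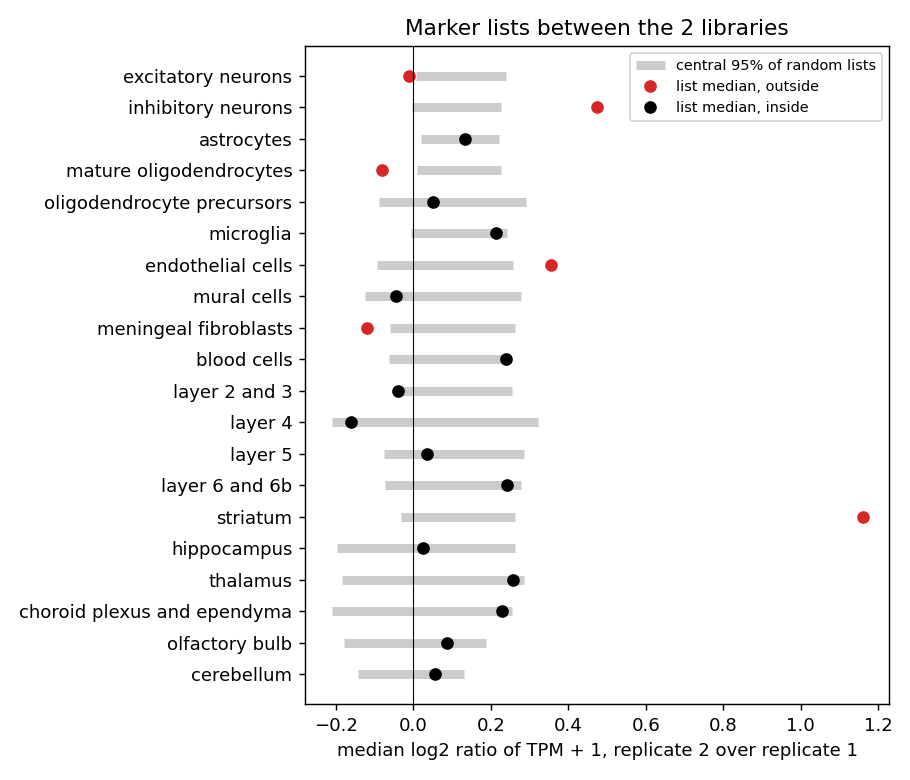
Median log2 ratio of TPM + 1 (replicate 2 over replicate 1, x axis) of 20 marker lists, as points, with the central 95% of random lists matched on expression as grey bars. The striatum list, at 1.16, lies farthest from its random lists.

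The single genes with the lowest ratios included Acta2 and several collagen and matrix genes, and Col1a1 and Col1a2 were among them. The secreted matrix glycoprotein gene Thbs1 (ENSMUSG00000040152.8, chromosome 2, 118111876 to 118127133) had a TPM of 19.5 in replicate 1 and 0.570 in replicate 2, and was higher in replicate 1 by 34.2-fold (95% counting interval 24.2 to 49.9). The smooth muscle actin gene Acta2 was at -3.27, and Spp1, Col3a1 and Bgn were at -1.96, -1.91 and -1.87. The transfer RNA gene mt-Tn was at -2.21. Rps26-ps1 at -3.68 and Iqschfp at -1.99 shared 73.7% and 98.5% of their 36-nucleotide words with other genes, so their values are uncertain. The 10 highest ratios were Gm4613, Gm8430, Rpl9-ps7, Gm3362, Gm10273, Gm15616, Rpl10-ps3, Gm10736, Gm3699 and Gm10180, from 6.27 down to 1.77. All 10 shared 52.1% to 100% of their words with other genes, and their ratios are uncertain for that reason.

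Mitochondrially encoded protein genes were lower in replicate 2, with a median log2 ratio of -0.47 and 12 of 13 members lower. Mitochondrially encoded genes together took 14.9% of the counts in replicate 1 and 11.5% in replicate 2. The ratio of depth-scaled counts of mt-Atp6, which like mt-Nd4l was chosen after its value was seen, was 0.357. With its nuclear copy Gm10925, with which it shares nearly all of its sequence, the ratio was 0.655. The member that was higher, mt-Nd4l, had a ratio of 1.54, and 0.959 with its nuclear copy Gm10222.

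Leading transcripts matched between the libraries for most genes. Of 7429 genes with at least 2 transcripts and TPM 5 in both libraries, 5669 (76.3%) had the same leading transcript in both. The leading transcript held a median of 47.0% of the gene's TPM, and in 2259 genes its deposited interval lay above that of every other transcript in both libraries. The lead of the pyruvate kinase gene, Pkm-202, held 91.9% ± 2.53 of the gene's TPM, Plp1-202 held 78.6% ± 1.85, Snap25-201 held 70.6% ± 4.70, Bin1-202 held 65% ± 0.962 and Cdc42-201 held 60.8% ± 2.23. Lower shares were held by Ntrk2-201 (51.9% ± 1.17), Bdnf-209 (50.1% ± 11.5), Mapt-204 (47.2% ± 0.552), Syp-201 (40.2% ± 1.10), Camk2a-203 (40.1% ± 1.80), Dlg4-210 (32.4% ± 10.7), Nrxn1-207 (30.9% ± 0.523), Rtn4-204 (27.4% ± 4.64), Dnm1-205 (26.6% ± 2.76), Grin1-206 (23.2% ± 4.27) and Homer1-204 (20.9% ± 4.00). The intervals of the Ntrk2, Bdnf, Dlg4, Rtn4, Dnm1, Grin1 and Homer1 leads did not lie above every other transcript's in both libraries. Those leads are uncertain for that reason. For Gria2 and Mbp the leads were a retained-intron transcript, Gria2-208 (41.4% ± 1.85), and a noncoding transcript, Mbp-214 (34.98% ± 1.94). App had 1 transcript in the files. The leading transcript of Clta differed between the libraries, with Clta-206 in replicate 1 and Clta-202 in replicate 2.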

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

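No test of this part was chosen after its result was seen. Rows outside the main measurement held counts above the limit of 3 that a count of 0 allows. The spike-in rows summed to 7.67 expected counts in replicate 1 and 11 in replicate 2, although the labels name spike-ins. The numbered short rows summed to 6039 and 4525 expected counts.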

How the results depend on the processing

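The alternatives for protein-coding genes with 100 or more counts, GC content, rescaling over nuclear protein-coding genes and single genes were chosen after seeing the data. No paired analysis was possible because there is 1 group, and a single library gives no value between libraries. The number of detected genes stayed within 1.5 times in all alternatives. The spread between libraries, which has no replicate error, was 0.202 with a pseudocount of 0.1, 0.130 with TMM, 0.130 with DESeq2 size factors, 0.155 from TPM 10, 0.139 with posterior means, 0.154 for protein-coding genes with 100 or more counts and 0.148 after the GC adjustment. Genes over 2-fold apart numbered 1091, 168, 102, 1263, 396 and 44 with a pseudocount of 0.1, TMM, TPM 10, no filter, posterior means and protein-coding genes with 100 or more counts, against 712. These TMM values, and the spread with DESeq2 size factors, use CPM + 1 without correction for length, so they change more than the scaling. The coefficient of variation was 0.168 by DESeq2, which also gave 0.162 for 0.1 put in, 0.102 unfiltered and 0.0916 without mitochondrial genes. Leading transcripts matched in 2993 genes at TPM 20, where fewer genes qualify.

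With posterior means, the median TPM was 56.1 for excitatory neurons, 61.4 for astrocytes, 66.7 for mature oligodendrocytes, 7.79 for precursors, 19.5 for microglia and 4.46 for endothelial cells. Without mitochondrial genes, in which case TPM is scaled up by construction, it was 81.7, 89.1, 96.0, 11.3, 28.3 and 4.48 in that order, 30.2 for inhibitory neurons and 22.7 for blood cells. The geometric mean was 84.0, 83.7, 66.8, 8.71, 15.7 and 4.51 in that order, and 7.75 for blood cells. In a single library the median ranged from 18.4 to 24.7 for inhibitory neurons, 66.2 to 69.5 for astrocytes, 70.0 to 71.2 for mature oligodendrocytes, 19.8 to 21.6 for microglia and 4.45 to 14.1 for meningeal fibroblasts.

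Of the 12 lists outside the central 95%, 7 stayed outside in all alternatives: inhibitory neurons, mature oligodendrocytes, endothelial cells, striatum, neuropeptides, cytosolic ribosomal proteins and RNAs without a poly(A) tail, the last with an uncertain percentile. The other 5 moved inside at least once. These were excitatory neurons at -0.0258 with the mean over members, progenitors at -0.21 with a pseudocount of 0.1 and -0.13 with the mean, GABA-A subunits at 0.0276 with the mean and -0.0470 with GC, Y-linked genes at -0.14 with TMM and -0.15 with GC, and meningeal fibroblasts at -0.17 with GC. Of the 23 lists inside, 7 moved outside at least once. Blood cells reached 0.33, 0.28 and 0.19 with a pseudocount of 0.1, the mean and the rescaling, cerebellum 0.49 and 0.25 with the pseudocount and the mean, mural cells -0.57 and thalamus 0.36 with the mean, hippocampus -0.26 and immediate early genes 0.13 with TMM, and layers 2 and 3 -0.19 with GC. The mitochondrially encoded list was at -0.56 with TMM, -0.41 with the mean, -0.45 with posterior means and -0.60 with the rescaling. Except where stated, the cause was not tested.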

Other observations

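The explanations for all 3 patterns, the 10 further gene lists and the genes named here were chosen after the patterns were seen. Bounds were written for 7 of the 10 lists before their values were computed, and the matrix, skeletal muscle and keratinocyte lists had none. The 2 fibroblast explanations were added only after the other 3 for the same pattern had been tested, and the sums without the member with the most counts and the comparison with other lists were added last.

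Connective tissue genes beyond the fixed lists were lower in replicate 2. Of 15 matrix genes, 12 were lower, with a median log2 ratio of -0.56, and their summed, depth-scaled count in replicate 2 was 0.466 (95% counting interval 0.436 to 0.497) of that in replicate 1. The crosslinking enzyme gene Lox, named after its value was seen, had a TPM of 5.07 in replicate 1 and 0.0800 in replicate 2, while Col6a1 was not lower, with 9.20 in replicate 1 and 9.34 in replicate 2. Skeletal muscle genes had a median log2 ratio of -0.01 at the 33.6 percentile, and keratinocyte genes 0.12 at the 98.3 percentile, with 3 of 5 keratinocyte genes under TPM 1 in both libraries.

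Striatal genes were higher in replicate 2, with a ratio of 2.16 (95% counting interval 2.08 to 2.24) in summed, depth-scaled counts. With TMM-scaled counts the list's median log2 ratio was 1.15, but the TMM factors of 0.994 and 1.006 could hardly change it, so that test cannot decide on scaling. Scaling shifts all genes alike, and it is argued against by the median log2 ratio of all genes, 0.10 against 1.16 for the list. More cortical interneurons are argued against by a median of 0.10 for the interneuron list, which shares Sst, Vip, Pvalb and Lhx6 with the inhibitory list. A second list of 20 striatum-enriched genes, none of them in the first, had a median of 0.82 at the 100th percentile, with 19 of 20 higher and 13 at TPM 1 or more in both libraries. These values are consistent with more striatal tissue in the replicate 2 piece, although Ebf1 was lower at -0.60. A difference in the cortex itself was not tested, and the shared donor identifier leaves unclear whether the libraries come from 1 or 2 animals.

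Acta2 at -3.27, Tagln at -1.58 and several collagen genes were lower in replicate 2, while the mural list, at the 10.2 percentile, and a further list of 9 smooth muscle genes, at the 14.6 percentile, lay inside the random lists. With the mean over members in place of the median, the mural list was at -0.57 and lay outside, at the 0 percentile. Arachnoid and pial genes and bone-forming genes had summed ratios of 1.11 (95% counting interval 0.968 to 1.29) and 0.934 (95% counting interval 0.795 to 1.10). Without the member with the most counts they were 1.20 (95% counting interval 1.03 to 1.41) and 1.05 (95% counting interval 0.862 to 1.29). These ratios argue against a large amount of either tissue on the replicate 1 piece. The lists had a median TPM of only 1.095 and 0.360, with 4 of 12 and 5 of 9 members under TPM 1 in both libraries. Such sums can hold RNA of the cortex itself, so a small amount is not excluded. The fixed meningeal list, with Col1a1 and Col1a2, had 5 of 9 members lower and 4 higher. A further list of 18 fibroblast genes had a median log2 ratio of -0.52 at the 0 percentile, with 15 of 18 lower and 9 at TPM 1 or more in both libraries, so RNA of fibroblasts in the replicate 1 library may have contributed, although its most abundant member Tpm1 was at 0.01 and the fibroblast gene Dcn at 0.56. A large vessel stays open, since the further smooth muscle list had a summed ratio of 0.924 (95% counting interval 0.809 to 1.05) but 0.768 (95% counting interval 0.629 to 0.937) without Mylk, with 5 of 9 members lower, 2 of them over 2-fold. Endothelial and blood cell genes were higher in replicate 2, with summed ratios of 1.17 (95% counting interval 1.08 to 1.26) and 1.37 (95% counting interval 1.26 to 1.49). No bound for the vessel was written for those lists. A trunk origin stays open too, since the 15 Hox genes summed to 25 and 9 counts, a ratio of 0.320 (95% counting interval 0.132 to 0.709) whose interval crosses the bound of 0.67.

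Gene ratios spread beyond counting noise. Transcript length is argued against by a Spearman rho of -0.0307 with the log2 ratio across 11255 nuclear protein-coding genes. GC content stays open as a part, with a rho of 0.226 that lies between the bounds of 0.1 and 0.3, and the median ratio ran from -0.04 at 38.0% GC to 0.19 at 62.9% GC. A different mix of cell types or neighbouring tissue as a general cause stays open. Of the 16 cell type and region lists, 6 lay outside the central 95%, which reached the bound of 4 written for this cause. In the comparison added last, 6 of the 19 other lists lay outside too, 31.6% against 37.5%. The shares are close, so the count does not single out cell type and region lists. Of the other lists that hold cell type genes, neuropeptides lay outside, but the layer lists all lay inside. RNAs without a poly(A) tail, whose percentile is uncertain, are among the other lists outside. A difference in the cortex itself was not tested.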
